A study of Mus musculus with 24 samples.

How the data were processed

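CUT&RUN profiles of PRDM16, H3K4me1 and H3K4me2 were analysed in mouse ES cells and in day 6 embryoid bodies (EB) of C57BL/6 background, each in wild type and Prdm16 KO. CUT&RUN cuts chromatin with an antibody-tethered nuclease and sequences the released fragments. The 24 libraries formed 12 groups of 2 libraries, with group and replicate number taken from the sample titles. The labels do not say that the 2 libraries of a group came from separate cultures. Exact permutation p-values over libraries therefore measure only the spread between these libraries, which may be technical. P-values of Fisher's tests, peak shifts and gene draws take genes, regions or peaks as units and measure no spread between libraries. The titles also name 3 library series: 20 libraries share 1 series, and 2 libraries belong to each of the others.

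Each library had 1 deposited list of peaks, called per library and holding chromosome, start, end, a MACS peak name and a score. The score of each peak is the authors' own value as deposited, its unit is not given in the sources used here, and it was at least 50 in each list. It has the form of the values MACS reports, and it was used only to rank or filter peaks within a list. Per the submitters' processing notes, the genome build was mm10 and the tools were Bowtie2, SAMtools 1.5, bedtools, MACS2, deepTools and HOMER 4.10, with no role or order given. The use of a control library in peak calling, the treatment of duplicate reads and any scaling for depth are not given in the sources used here. Read totals were not analysed here, so the depth of each library is unknown. Differences in peak number can therefore reflect depth and background as well as the amount of a mark. Peak numbering had no gaps in any list.

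Peaks on chromosomes 1 to 19, X and Y were kept, which set aside the 1 mitochondrial peak in each list. Within each set of 4 libraries of 1 antibody and stage (or of the 4 wild-type libraries of 1 antibody), overlapping peaks were merged into regions. A library had a region when a peak overlapped it by at least 1 bp. A region in both wild-type and neither KO library is called wild-type-only, the reverse KO-only, and ES-only and EB-only are used likewise. The number of such regions was set against the numbers in the other choices of 2 of the 4 libraries, which pair 1 library of each group. A count inside the range of the other choices does not set the genotypes apart, and regions named from it need not differ with genotype. Peak numbers were compared on the log2 scale with a two-sided exact permutation test over the 6 assignments of 2 and 2 libraries, whose smallest possible p is 0.333. The difference of the KO effect between stages was tested by exact permutation of genotype within antibody and stage over both H3K4me antibodies. Joint loss of both marks was tested with Fisher's exact test over regions, and with a Mantel-Haenszel odds ratio within 5 strata of wild-type score rank. PRDM16 peaks were compared with 1000 random circular shifts along their chromosomes, one-sided. Intervals are 95% Wilson intervals and cover counting error only.

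Genes were taken from a RefSeq table of the GRCm38.p6 assembly, which has the coordinates of mm10, with 21887 protein-coding genes. The table used here gives gene start and end without strand or exons. The planned window of 2500 bp either side of a transcription start was therefore replaced by 2500 bp either side of each gene end, and exon, intron and UTR were not resolved. A gene was marked in a library when a peak overlapped either window. All 288 genes of 15 lists, written before the data were examined, matched the table. The lists cover naive pluripotency, primed epiblast, neuroectoderm, primitive streak and mesoderm, cardiac, blood and endothelial, endoderm and trophoblast markers, brown fat genes linked to PRDM16, H3K4 methylation enzymes, PRDM family genes, housekeeping genes, fibroblast or feeder markers, mature tissue genes and Hox genes. Each list was tested with a two-sided Fisher's exact test per antibody, stage and direction. The background for KO loss was genes marked in both wild-type libraries, and for KO gain genes marked in neither. For the stage comparison it was genes marked in both libraries of the stage tested. Benjamini-Hochberg adjustment covered 120 KO tests and 60 stage tests, and odds ratios had 0.5 added to each cell.

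The text names list members, and for each comparison and direction the 10 regions at a protein-coding gene end with the highest rank of the lower of the 2 scores. PRDM16 sites are named by the nearest protein-coding gene. This rule was fixed before the data were examined, and any other named gene or region was chosen after its values were seen. Alternatives fixed at that time were the higher-scoring 50% of each list, equal list lengths, covered base pairs, merging within 1000 bp, coverage of 50% of a region, every contig, each library left out, the replicate number as a block, the library series, each antibody alone, other strata and shifts, and gene windows of 1000 and 10000 bp. A score of at least 100 and the whole gene span were added after seeing the data.

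Overlap and merging gave the same counts as bedtools 2.31.1 on a pair of lists, and the region step was tested on simulated lists with 200 regions planted in each direction, drawn at the replicate overlap of each set. It recovered 74% of planted losses and 67.5% of planted gains for H3K4me2 in ES cells, and 66.5% and 62.5% in EB. For H3K4me1 it recovered 32.5% and 33.5% in ES cells and 27.5% and 25% in EB. Of unchanged regions, 1.81% and 1.95% were misplaced per direction for H3K4me2 in ES cells and EB, as the mean of both directions. For H3K4me1 these rates were 5.54% and 6.14%. Every region of a set had the same detection rate in the simulation, so these rates need not hold for the real lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.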

Results

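PRDM16, H3K4me1 and H3K4me2 were profiled by CUT&RUN in mouse embryonic stem (ES) cells and in day 6 embryoid bodies (EB), aggregates of differentiating ES cells, in wild type and Prdm16 KO. PRDM16 is a zinc finger protein of the PR domain family, and H3K4me1 and H3K4me2 mark enhancers and promoters. Each of the 12 groups held 2 libraries. H3K4me2 lists held 13818 to 32874 peaks covering 39.1 to 81 Mb, and H3K4me1 lists held 5990 to 15435 peaks covering 13.1 to 37.1 Mb. PRDM16 lists held 146 to 586 peaks covering 0.192 to 0.364 Mb. Coordinates are mm10. A peak list records where a peak was called, and several highly active genes had none: Gapdh, Nanog, Pou5f1 and Polr2a had no H3K4me2 peak within 2500 bp of a gene end in either wild-type ES library. Lack of a peak was therefore not read as lack of the mark. With 2 libraries per group, the smallest possible two-sided exact permutation p for a KO effect on peak number was 0.333.

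**Figure D1:**
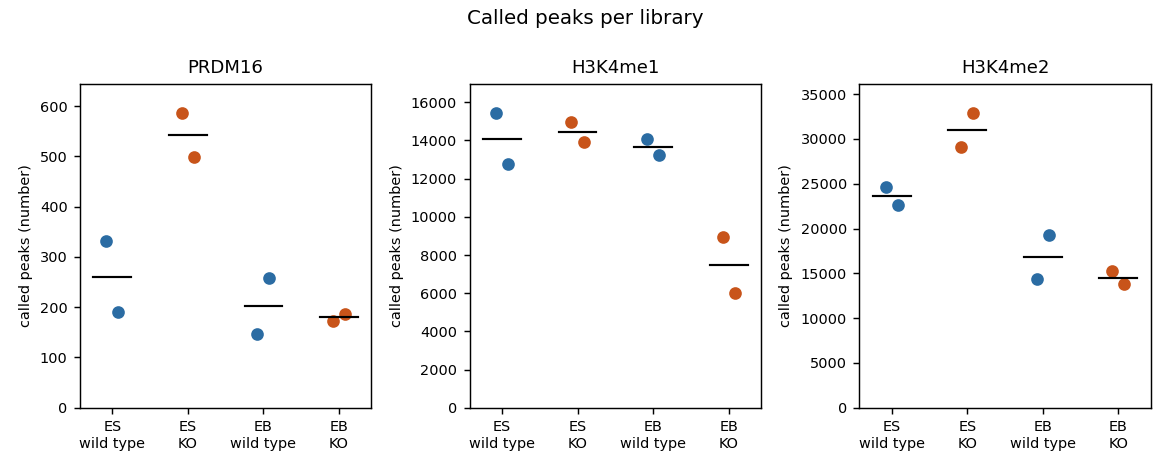
Number of called peaks by antibody, stage and genotype, with 1 point per library, wild type in blue, KO in orange and a line at each group mean. H3K4me1 in EB had 14082 and 13260 peaks in wild type and 8943 and 5990 in KO, and H3K4me2 in ES cells had 24600 and 22615 in wild type and 29138 and 32874 in KO.

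The targeted gene was examined first in all libraries. Prdm16 lies on chromosome 4 at 154316122 to 154637360. Around it, H3K4me2 in ES cells had 8 and 6 peaks in wild type, covering 13.2 and 11.1 kb, and 11 and 13 peaks in KO, covering 30.2 and 25.8 kb. In EB it had 3 and 4 peaks in wild type, covering 6.10 and 8.90 kb, and 0 and 0 peaks in KO. A site at 154438024 to 154440419, inside the gene span, had a peak in both KO and neither wild-type ES library. A site at 154472115 to 154473874 had a peak in both wild-type and neither KO EB library, while H3K4me1 had a peak over it in both KO and 1 wild-type EB library. Both sites were chosen after their values were seen. H3K4me1 peaks there numbered 6 and 4 in wild-type and 7 and 6 in KO ES cells, and 3 and 4 in wild-type and 6 and 3 in KO EB. PRDM16 had 0 peaks there in its 8 lists. These peaks spread over the gene and do not test the deletion itself, so the KO labels were not checked by the files.

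**Figure D2:**
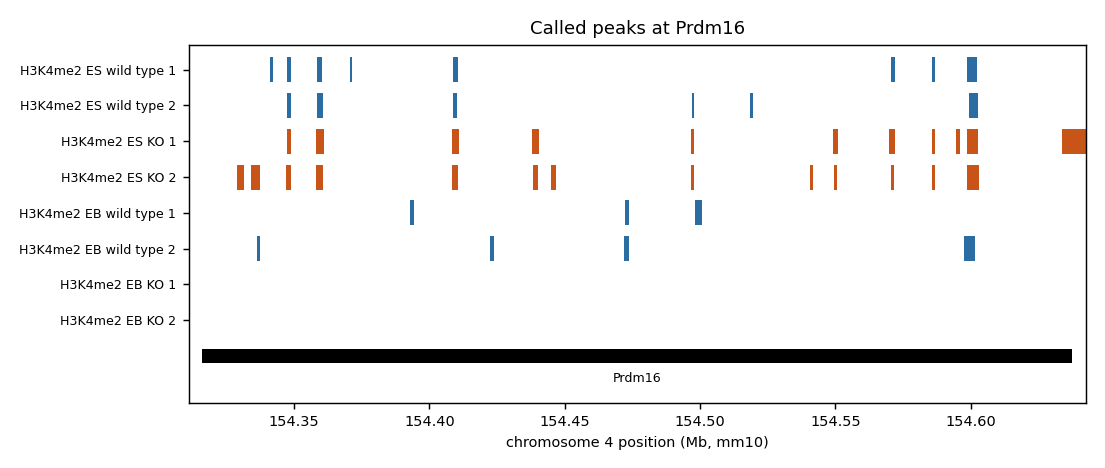
H3K4me2 peaks around Prdm16 on chromosome 4 (position in Mb on the horizontal axis) in 8 libraries, 1 line per library, with each box a called peak and the gene as a black bar. Wild-type EB libraries had 3 and 4 peaks and KO EB libraries 0 and 0, while ES libraries had 8 and 6 in wild type and 11 and 13 in KO.

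The PRDM16 antibody in KO cells served as background for PRDM16 in wild type. Sites near the top of the score rank were shared by both genotypes, and 40 regions had a peak in all 8 PRDM16 lists. Of these, 20 also had one in all 16 H3K4me lists. They included chromosome 2 at 98665745 to 98667799, 1034072 bp from an end of its nearest gene, Lrrc4c. Another was chromosome 17 at 39842600 to 39849283, 101236 bp from Esp38. Other sites lay 281338 bp from Pex2, 20652 bp from Ly6c2, 2487 bp from Mid1 and 1388 bp from Brox. A site with a peak for every antibody in both genotypes is not specific to PRDM16. Of 1693 PRDM16 regions, 1491 (88.1%) were in 1 list, 1 was in all 4 wild-type and no KO lists, and 0 were the reverse.

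In ES cells, PRDM16 had 261 ± 99 peaks in wild type and 543 ± 61.5 in KO (SD, n = 2 each), 2.15-fold more in KO (two-sided exact permutation p = 0.333). KO had more peaks than wild type in each library series, with 331 and 499 peaks in one and 191 and 586 in the other. Regions with a peak in both wild-type and neither KO library, called wild-type-only, numbered 9, and those with the reverse, KO-only, numbered 29, with 5 to 11 in the other choices of 2 libraries. Wild-type-only sites lay at Pask on chromosome 1 (93342594 to 93343733) and near Dok2 and Scyl3, and KO-only sites inside Tusc3 and Ncor1 and at the ends of Lrrc56 and Ankrd10. In base pairs covered, the KO over wild-type log2 ratio was 0.27, and with equal list lengths it was -0.48. In EB, PRDM16 had 202 ± 79.2 peaks in wild type and 180 ± 9.9 in KO, a log2 ratio of -0.11 (exact permutation p = 1, n = 2). The 9 wild-type-only regions, equal to the highest of the other choices, included sites at Ing1 and in Rnf126, and the 1 KO-only region lay near Zfp239.

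PRDM16 peaks lay over regions with an H3K4me1 or H3K4me2 peak in both wild-type libraries more often than shifted positions did, in both genotypes. In ES cells 36.0% and 46.1% of wild-type and 28.0% and 27.9% of KO peaks did so, against 4.23% to 5.05% of shifted peaks, a wild-type mean of 41.0% ± 7.16 and a KO mean of 27.9% ± 0.0924 (SD, n = 2, two-sided exact permutation p = 0.333). In EB the shares were 43.8% and 53.1% in wild type and 46.8% and 34.8% in KO (exact permutation p = 0.667). For each of the 8 libraries the one-sided p against 1000 shifts was 0.000999, the smallest they can give. The 40 regions in all 8 PRDM16 lists had a peak in a median of 15.5 of the 16 H3K4me lists. Of the 1491 regions in 1 PRDM16 list, 843 had a peak in no H3K4me list. The shift test kept the sites shared by all antibodies, so the excess does not show PRDM16 binding at H3K4me regions.

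In ES cells the question for H3K4me2 was where called regions differed between KO and wild type. KO-only regions numbered 4468 and wild-type-only regions 695, against 183 to 809 in the other choices of 2 libraries, among 38049 regions. The wild-type-only count lay within that range, so the genes named from it need not differ with genotype. KO-only regions were narrow and mostly away from gene ends, with a median width of 1426 bp and 13.5% within 2500 bp of one, against 4904 bp and 45.9% for wild-type-only regions and 3261 bp and 54.9% for regions in all 4 lists. KO-only regions at gene ends included Dnah11, an axonemal dynein gene (chromosome 12, 118197933 to 118199431), Dcaf12l2, Ormdl2, Islr and Copg1. Wild-type-only regions included Cpne9, Mmp15, a membrane matrix metalloproteinase, Arntl2, a clock gene, Bcar3, Dpf3 and Mecom, a PR domain gene related to Prdm16 (chromosome 3, 30506367 to 30511901). Peak number was 23608 ± 1404 in wild type and 31006 ± 2642 in KO (SD, n = 2), a log2 ratio of 0.39 (exact permutation p = 0.333). In 5 equal groups of KO regions by score rank, 49.8% of the weakest group were KO-only and 0.077% of the strongest. With equal list lengths 1659 regions were KO-only and 1450 wild-type-only, and KO replicate 2 is of another library series, without which the counts were 6751 and 1706 under a criterion that 1 KO library can meet.

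**Figure D3:**
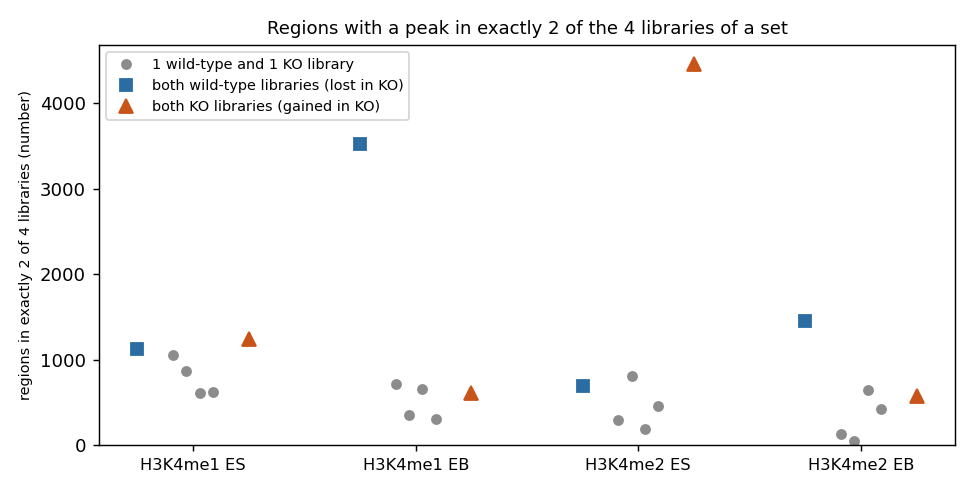
Number of regions with a peak in exactly 2 of the 4 libraries of each H3K4me set, with squares for both wild-type libraries, triangles for both KO libraries and grey points for 1 library of each. H3K4me2 in ES cells had 4468 KO-only regions and H3K4me1 in EB 3520 wild-type-only regions, against at most 809 and 710 in the other choices.

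In EB, H3K4me2 wild-type-only regions numbered 1455 and KO-only regions 577, against 41 to 640 in the other choices. Wild-type-only regions included Lrif1 (chromosome 3, 106684394 to 106686373), Gabrg1, a GABA receptor subunit, Cartpt, a neuropeptide precursor, Jakmip2 and Mapk10. KO-only regions were wider than wild-type-only regions, with a median of 4634 bp against 2214 bp, and 70.4% lay at gene ends against 24.8%. In this they were closer to regions in all 4 lists, with a median of 4176 bp and 80.8% at gene ends. KO-only regions included Dtx4, Atoh1, a proneural transcription factor (chromosome 6, 64727135 to 64731527), Jag1, a Notch ligand, and Nxph1 and Lrrc4. Peak number was 16790 ± 3473 in wild type and 14512 ± 981 in KO (log2 ratio -0.20, exact permutation p = 0.667, n = 2). Without wild-type replicate 2, the library of another series, it was 0.02 and KO-only regions numbered 1279.

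In ES cells, H3K4me1 wild-type-only regions numbered 1129 and KO-only regions 1241, against 604 to 1056 in the other choices. Both counts were little above that range. The simulated misplacement of 5.54% per direction would give more than either count among 26140 regions. The genes named here therefore need not differ with genotype. Wild-type-only regions included Lratd2, the zinc finger transcription factor genes Sp9 and Osr2, and Flnc, a filamin, and KO-only regions included Serpinb6c, Dapp1, Nabp1 and Vrk1. Peak number was 14091 ± 1901 in wild type and 14423 ± 738 in KO, a log2 ratio of 0.04 (exact permutation p = 1, n = 2).

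In EB, H3K4me1 had 13671 ± 581 peaks in wild type and 7467 ± 2088 in KO, 1.87-fold more in wild type (log2 KO over wild type -0.90, exact permutation p = 0.333, n = 2). Wild-type-only regions numbered 3520 and KO-only regions 609, against 301 to 710 in the other choices, among 24731 regions. The KO lists shared a mean of 43.0% of peaks with each other and 50.3% with wild-type lists, and wild-type lists shared 55.2% with each other. These shares also depend on list length. Median scores were 68.8 and 65.9 in KO and 74.4 and 73.5 in wild type, so the KO lists were weaker and less reproducible. Wild-type-only regions included Arhgef11 (chromosome 3, 87617971 to 87621565), Hes3, a Hes family repressor of the Notch pathway (chromosome 4, 152289597 to 152295045), Zp2, Bcl9, a Wnt pathway cofactor, Zbtb16 and Cyp24a1. Of the wild-type-only regions 22.8% lay at gene ends, and KO-only regions at gene ends included Atf3, a stress response factor, Frmd8, Tuft1, Ccng2 and Kcna5. In 5 equal groups of wild-type regions by score rank, 65.7% of the weakest and 25.5% of the strongest group were wild-type-only. With equal list lengths the counts were 1193 and 868.

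**Figure D4:**
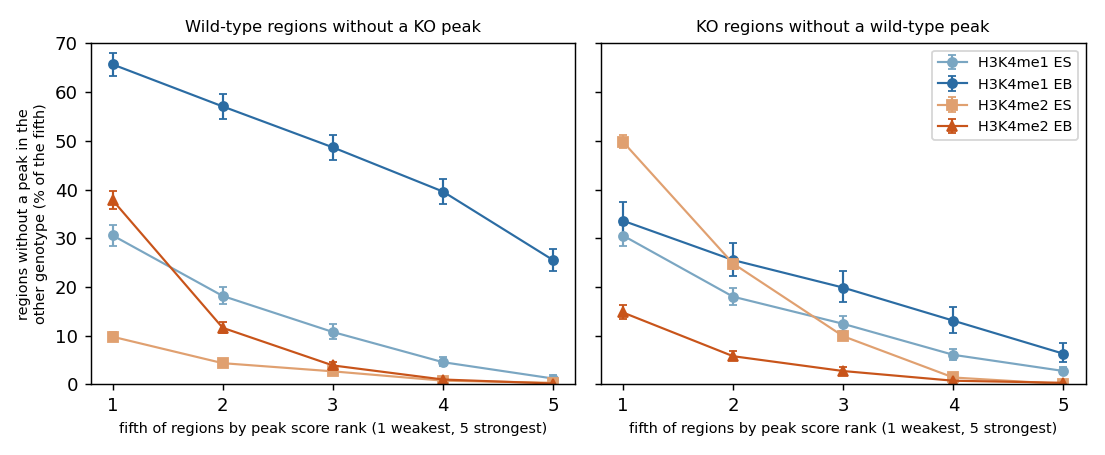
Percent of regions in both wild-type (left) or both KO (right) libraries that had no peak in either library of the other genotype, in 5 equal groups by score rank from weakest to strongest, with 95% Wilson intervals that cover counting error only. For H3K4me1 in EB, wild-type-only regions went from 65.7% in the weakest group to 25.5% in the strongest, and for H3K4me2 in ES cells, KO-only regions went from 49.8% to 0.077%.

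Whether the KO effect differed between stages was tested over both marks. The log2 KO over wild-type peak number was higher in ES cells than in EB by 0.76 (two-sided exact permutation p = 0.0123, 1296 assignments, smallest possible 0.00154). Genotype was shuffled separately for each antibody, as if their libraries were independent, which the labels do not show. The p measures departure from no KO effect at either stage, not from an equal effect at both. By mark, the ratio was 0.39 in ES cells and -0.20 in EB for H3K4me2, and 0.04 and -0.90 for H3K4me1. For 1 mark alone, the differences were 0.59 for H3K4me2 (exact p = 0.111) and 0.94 for H3K4me1 (exact p = 0.167). A test of 1 mark has too few assignments to give a p under 0.05, so these values decide nothing. The H3K4me2 libraries of another series, ES KO replicate 2 and EB wild-type replicate 2, had the most peaks of their sets, with 32874 and 19246, and both raise this difference. Without them it was 0.61 (exact p = 0.0463), with ratios for H3K4me2 of 0.30 in ES cells and 0.02 in EB.

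Loss of both marks at the same regions was asked at regions with both marks in all wild-type libraries of a stage. In ES cells, 4991 regions had both, 557 had no H3K4me1 peak and 153 no H3K4me2 peak in either KO library, and 48 had neither peak, with 17.1 given by chance (Fisher's exact test, two-sided p = 5.9e-12). Within strata of peak strength the odds ratio was 2.64 (95% interval 1.82 to 3.83). In EB, 2417 regions had both, 888 had no H3K4me1 peak and 537 no H3K4me2 peak in either KO library, and 216 had neither, with 197 given by chance (Fisher's exact p = 0.0605), an odds ratio of 1.01 (0.823 to 1.24). The EB value was unstable: without H3K4me1 wild-type replicate 1 it was 0.780, without replicate 2 0.758, without H3K4me2 KO replicate 1 0.772 and without H3K4me2 wild-type replicate 1 1.33, each past the threshold, and with 50% of the region covered 1.85. The ES value was 1.70 with 50% covered, which no longer passed. The ES over EB ratio of these odds ratios was 2.61 with any overlap but 0.92 with 50% covered, so no stage difference in joint loss is concluded. Regions are not independent replicates.

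Hox genes, which pattern the body axis, had fewer H3K4me2 peaks in KO ES cells. Of 20 Hox genes marked in both wild-type libraries, 6 were wild-type-only: Hoxd12 and Hoxd11 (chromosome 2), Hoxd4, Hoxa13 (chromosome 6) and Hoxb13 and Hoxb4 (chromosome 11). These 6 genes lay at 5 regions. Of other genes, 260 of 11194 were wild-type-only (odds ratio 18.8, Fisher's exact test, two-sided, adjusted p = 0.000592). This list alone of 15 passed among 120 tests, of which 7 had an unadjusted p under 0.05. Its call ended with a window of 10000 bp (exact test, adjusted p = 1), with the higher-scoring 50% of peaks and with scores of at least 100. Other values that did not pass were H3K4me1 at Hox genes in ES cells, 5 of 10, including Hoxd9, Hoxb8 and Hoxc11 (exact test, adjusted p = 0.164), against 1 KO-only of 18, Hoxb13, which had H3K4me1 in both KO and neither wild-type ES library (exact test, adjusted p = 1), and H3K4me2 in EB at Hoxd4 and Hoxb1, 2 of 4 (exact test, adjusted p = 0.164). The last value turned on single libraries: it was 9 of 14 without wild-type replicate 1 (exact test, adjusted p = 1.1e-05) and 3 of 5 without replicate 2, the library of another series (exact test, adjusted p = 0.0399).

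**Figure D5:**
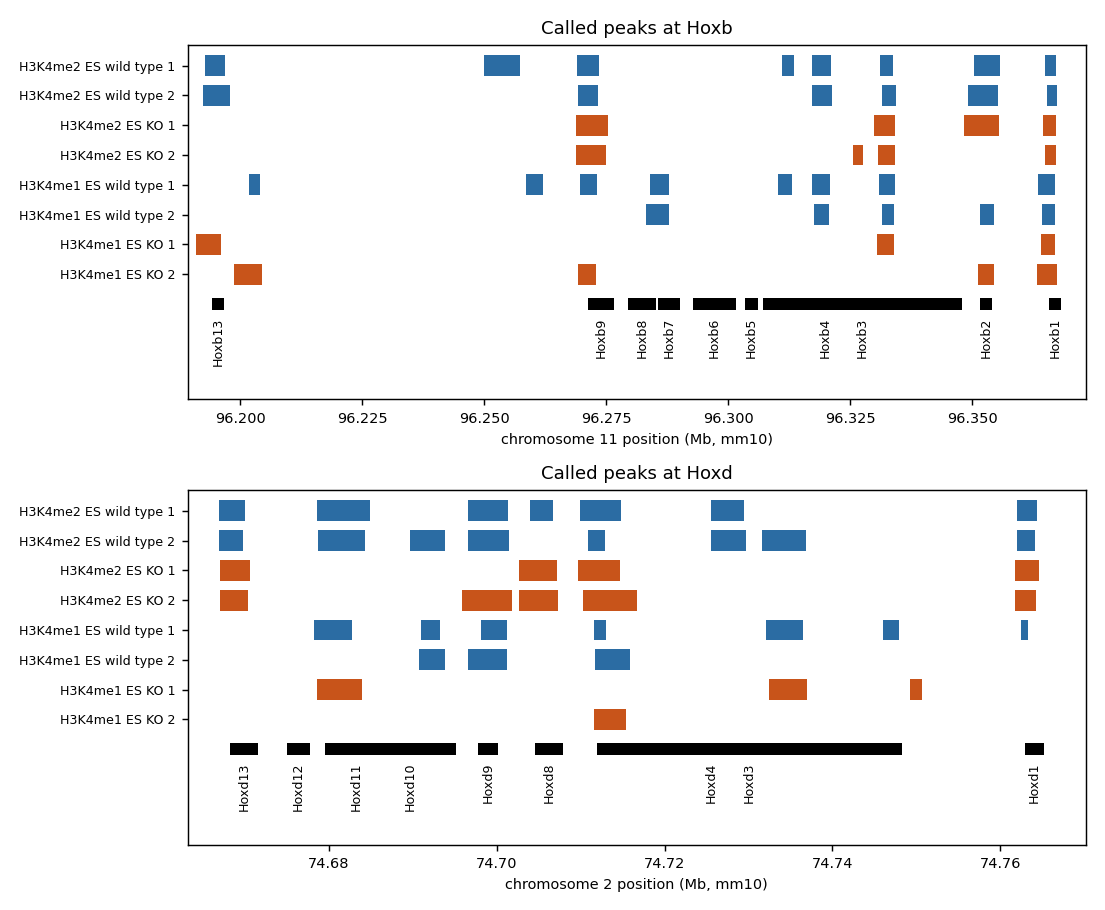
H3K4me1 and H3K4me2 peaks at the Hoxb and Hoxd clusters in ES cells (position in Mb on the horizontal axis), with 1 line per library, each box a called peak and genes as black bars. H3K4me2 covered 32.5 and 24.7 kb of the Hoxb cluster in wild type and 20.6 and 13.9 kb in KO. At the Hoxc cluster, not drawn, it covered 30.7 and 32.5 kb in wild type and 21.5 and 42.2 kb in KO, more in KO replicate 2 than in wild type.

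No other list passed in KO with the 2500 bp window and all libraries. The primitive streak list passed without H3K4me2 ES wild-type replicate 2 (6 of 12, exact test, adjusted p = 0.00124) and, with its own counts unchanged, without either H3K4me2 EB wild-type library (exact test, adjusted p = 0.0399). With 1000 bp, naive pluripotency (H3K4me1 KO-only in ES cells, 4 of 21, exact test, adjusted p = 0.0123) and primitive streak genes (H3K4me2 wild-type-only in ES cells, exact test, adjusted p = 0.0484) also passed. With 10000 bp, neuroectoderm genes passed as KO-only in EB for H3K4me1 (3 of 8, exact test, adjusted p = 0.0113) and H3K4me2 (6 of 14, exact test, adjusted p = 0.00377), and Hox genes as wild-type-only for H3K4me2 in EB (4 of 7, exact test, adjusted p = 0.00335). With the whole gene span, chosen after the results were seen, this Hox test and the primitive streak test passed beside the reported Hox call. With 2500 bp and all libraries, the primitive streak and mesoderm list had the next lowest value, with H3K4me2 wild-type-only in ES cells at Snai1, Eomes and Gsc, 3 of 9 (exact test, adjusted p = 0.0598), and these transcription factors act in gastrulation. In EB, Snai1 went the other way, with KO-only H3K4me2. Trophoblast markers Tead4 and Bmp4 had KO-only H3K4me1 peaks in ES cells (exact test, adjusted p = 0.164), but Tead4 was wild-type-only for H3K4me1 in EB and Gata3 for H3K4me2 in ES cells. Neuroectoderm genes, including Lhx2 and En2, had KO-only H3K4me2 in EB at 3 of 16 (exact test, adjusted p = 0.668), and the cardiac gene Nkx2-5 wild-type-only H3K4me2 in EB (exact test, adjusted p = 0.666). Primed epiblast genes Pou3f1 and Otx2 had KO-only H3K4me2 in EB and Dnmt3b KO-only H3K4me1 in EB, with a smallest adjusted p of 0.785 in the exact tests. The smallest adjusted p in the exact tests was 1 for naive pluripotency, blood and endothelial, endoderm, brown fat, H3K4 methylation, PRDM family, housekeeping, fibroblast or feeder and mature tissue genes. Wild-type-only and KO-only calls were added over the 4 sets, so Hoxb4, Hoxd4, Gsc and Prdm10 counted more than once. These calls numbered 13 and 1 for Hox, 6 and 1 for primitive streak and 4 and 1 for H3K4 methylation. They numbered 3 and 2 for endoderm, 1 and 0 for blood and endothelial, and 3 and 0 each for brown fat, cardiac and PRDM family lists. They numbered 1 and 4 for naive pluripotency, 2 and 4 for neuroectoderm, 1 and 3 for primed epiblast and 2 and 3 for trophoblast. They numbered 0 and 1 each for housekeeping and mature tissue, and 0 and 0 for fibroblast or feeder lists. Over all protein-coding genes they numbered 392 and 286 for H3K4me1 in ES cells and 906 and 127 in EB. For H3K4me2 they numbered 266 and 419 in ES cells and 358 and 448 in EB.

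In wild type, ES cells were compared with EB. For H3K4me1, 5412 regions were ES-only and 4679 EB-only, against 222 to 426 in the other choices, and for H3K4me2 6668 and 1807, against 38 to 502. Peak number had a log2 EB over ES of -0.04 for H3K4me1 (exact permutation p = 1, n = 2) and -0.51 for H3K4me2 (exact permutation p = 0.333, n = 2). For PRDM16 12 regions were ES-only and 2 EB-only, against 2 to 12, with a log2 ratio of -0.37 (exact permutation p = 0.667, n = 2). ES-only H3K4me1 regions at gene ends included Tmem123, Kdm7a, a histone demethylase gene, Otx2, a primed epiblast and anterior neural factor (chromosome 14, 48651019 to 48656387), and Nkx2-9, and EB-only regions included Meis3, Hes3, Zfp9 and Serpinf1. ES-only H3K4me2 regions included Efnb2, Nxph1, Lrrc4, Dtx4 and Efna5, and EB-only regions included Elk3, Jam2 and Tet2, a DNA demethylation enzyme gene (chromosome 3, 133541853 to 133546590).

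By list, 4 of 60 stage tests passed, all for H3K4me2 (7 had an unadjusted p under 0.05). Naive pluripotency genes were EB-only at 5 of 10, Prdm14, Tet2, Fgf4, Klf2 and Klf5 (odds ratio 14.0, Fisher's exact test, adjusted p = 0.0117), against 6.68% of other genes. Of 46 housekeeping and naive pluripotency genes, 32 lacked an H3K4me2 peak in 1 or both wild-type ES libraries, Gapdh and Polr2a among them. Neuroectoderm genes were ES-only at 5 of 9, including Lhx2, Pax7 and Zic1 (odds ratio 13.4, Fisher's exact test, adjusted p = 0.0117), against 8.35%, and Hox genes at 7 of 20, including Hoxd13, Hoxa13 and Hoxc10 (odds ratio 6.10, Fisher's exact test, adjusted p = 0.0168). Without EB wild-type replicate 2, the library of another series, the Hox value was 16 of 20 (odds ratio 21.2, exact test, adjusted p = 8.6e-09). Cardiac genes were ES-only at 3 of 4, Myl7, Isl1 and Gata4 (odds ratio 25.5, Fisher's exact test, adjusted p = 0.0331), a call that ended without ES wild-type replicate 1 (exact test, adjusted p = 0.0532) or EB wild-type replicate 2 (exact test, adjusted p = 0.175). It also ended with the 10000 bp window, the higher-scoring 50% of peaks, equal list lengths, scores of at least 100 and the whole gene span (exact tests, adjusted p of 0.0787 to 0.263). The Hox call ended with the 10000 bp window, the higher-scoring 50%, equal list lengths and the whole gene span (exact tests, adjusted p of 0.156 to 1), and the neuroectoderm call with the higher-scoring 50% (exact test, adjusted p = 0.0649). The naive pluripotency call passed under each alternative. Because the ES lists lacked peaks at many housekeeping and naive pluripotency genes, it does not show that the mark was gained in EB.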

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

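The tests of weak regions dropping out of the EB KO lists, of sensitivity of the ES KO libraries and of the Hox cluster share were chosen only after the result was seen. The log2 KO over wild-type peak number was higher in ES cells than in EB by 0.76 (exact permutation p = 0.0123), with each antibody shuffled separately as if independent. That p measures departure from no KO effect at either stage, so it does not show that the effect differed between stages. The difference was 0.61 without the 2 H3K4me2 libraries of another series, which both raise it. The ratio of the ES to the EB odds ratio of joint loss was 2.61 with any overlap, counted over regions, which are not independent replicates, but 0.92 with 50% of the region covered, so a stage difference in joint loss stays open.

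The first pattern is the 3520 H3K4me1 regions with a peak in both wild-type and neither KO EB library. Weak regions dropping out first remains open: of the weakest of 5 groups by score 65.7% had no peak in either KO list and of the strongest 25.5%, and how many of the strongest would be missed without a change is not known. An earlier limit of 10% for the strongest group, which would have excluded this cause, was given up after the 25.5% was known, because no such value stood behind it. Shorter KO lists remain open: with equal list lengths, wild-type-only over KO-only regions was 1.37. Equal lengths push both counts together whatever the cause, so this value does not decide between list length and genotype. A lower yield of the H3K4me1 KO libraries alone was not decided by the joint loss odds ratio of 1.01, because it was 1.85 with 50% of the region covered. Genotype remains among the open explanations.

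The second pattern is the 4468 H3K4me2 regions with a peak in both KO and neither wild-type ES library. Higher sensitivity of these KO libraries may explain it, since 0.077% of the strongest of 5 groups of KO regions lacked a wild-type peak. Longer KO lists also remain open. With equal lengths, KO-only over wild-type-only regions was 1.14. Equal lengths push both counts together whatever the cause, so this value decides nothing. H3K4me1, from other libraries, did not differ at most of the 4468 KO-only regions. It was in more KO than wild-type libraries at 847 and the reverse at 330. Where it differed it leaned to KO at 72.0%, against 44.9% of regions in all 4 H3K4me2 lists (odds ratio 3.15, Fisher's exact p = 1.5e-65, over regions) and 43.5% to 49.5% in the other choices of libraries. This is in line with a difference between the cells at part of these regions, a hypothesis found and tested on the same data.

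The third pattern is the 6 Hox genes whose H3K4me2 peak was in both wild-type and neither KO ES library. Loss of wide weak regions first would give up to 4 genes in 95% of draws matched on strength and width, below the 6 seen (permutation p = 0.0017), but neighbouring Hox genes share peaks, so the draws understate the spread. Across both marks and stages the share of covered base pairs in the 4 clusters had a mean log2 KO over wild type of -0.71 (exact permutation p = 0.00154, the smallest possible) and -0.68 without the H3K4me2 ES libraries (exact permutation p = 0.00926). The clusters were picked because their list stood out, and genotype was shuffled separately for each antibody. The test therefore does not show that the loss is real, and lower H3K4 methylation at Hox clusters in KO may be a hypothesis for new libraries.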

How the results depend on the processing

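Scores of at least 100, the whole gene span and every value quoted for them were chosen only after the result was seen; the other alternatives were planned. The cause of the changes was not tested, except where the construction shows it. Read depth is unknown, so its effect was not measured. Apart from the values below, 13 values of single gene lists that no longer passed under an alternative other than leaving out a library (5 of the cardiac, 4 of the Hox and 1 of the neuroectoderm stage calls and 3 of the Hox KO call), the cardiac stage call without ES wild-type replicate 1 or EB wild-type replicate 2, and the list tests that passed only under an alternative, results kept their direction and side of the threshold.

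With the replicate block, the stage by genotype difference stayed 0.76 (exact permutation p = 0.0391), and no call changed. The replicate numbers were not taken to pair libraries: replicate 1 deviated in the same direction in wild type and KO in 4 of 6 sets. By mark the difference was 0.94 for H3K4me1 alone and 0.59 for H3K4me2 alone, in tests with too few assignments to pass the threshold.

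Log2 KO over wild-type values in covered base pairs were 0.27 for PRDM16 ES and -0.48 for H3K4me2 EB; of the higher-scoring 50%, 0.32 and -0.48; with equal list lengths, -0.48 for PRDM16 ES, which reversed the direction, -0.20 for H3K4me1 EB and 0.063 for H3K4me2 ES. With scores of at least 100, peak number gave 0.47 for PRDM16 ES, -1.67 for H3K4me1 EB and 0.52 for H3K4me2 ES, and H3K4me1 ES changed sign within the spread between replicates, to -0.01 from 0.04. So did H3K4me2 EB without the second library series, to 0.02 from -0.20. The stage by genotype difference without that series was 0.61 (exact permutation p = 0.0463).

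Counts of wild-type-only and KO-only regions fell with fewer peaks by construction. With the higher-scoring 50% they were 3 and 18 for PRDM16 ES, 652 and 725 for H3K4me1 ES, 1823 and 347 for H3K4me1 EB, 287 and 2249 for H3K4me2 ES and 787 and 318 for H3K4me2 EB. With equal list lengths, PRDM16 ES had 9 KO-only, H3K4me1 EB 1193 wild-type-only, H3K4me2 ES 1450 and 1659, and H3K4me2 EB 924 wild-type-only regions. With scores of at least 100 they were 1 and 14 for PRDM16 ES, 1 and 0 for PRDM16 EB, 413 and 449 for H3K4me1 ES, 1053 and 79 for H3K4me1 EB, 316 wild-type-only for H3K4me2 ES and 175 KO-only for H3K4me2 EB. With 50% of a region covered, PRDM16 ES had 17 wild-type-only, PRDM16 EB 2 KO-only and H3K4me2 EB 2856 wild-type-only regions. Within a library series, PRDM16 ES had 245 and 411 or 95 and 482, and without the second series H3K4me2 ES had 1706 and 6751 and H3K4me2 EB 1279 KO-only regions, all under looser criteria.

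For ES-only and EB-only regions, the higher-scoring 50% gave 2885 and 2511 for H3K4me1, 2902 and 763 for H3K4me2 and 1 EB-only for PRDM16. Scores of at least 100 gave 1826 and 1256, 3648 and 1015, and 4 and 0. Equal list lengths gave 2737 H3K4me2 ES-only and 50% coverage 2871 H3K4me2 EB-only regions.

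The joint loss odds ratio in ES cells was 1.70 with 50% coverage and 2.75 with scores of at least 100, neither past the threshold, and in EB 1.85 with 50% coverage, past it. The ES over EB ratio of these was 2.61 as reported and 0.92 with 50% coverage. The number of passing KO list tests, 1 as reported, was 3 with a window of 1000 bp, 3 with 10000 bp, 0 with the higher-scoring 50% and with scores of at least 100, and 3 with the whole gene span. The number of stage list tests, 4 as reported, was 2 with the higher-scoring 50%, with equal list lengths and with the whole gene span. Stage tests that passed only under an alternative were Hox H3K4me1 ES-only with 10000 bp (16 of 21, exact test, adjusted p = 0.0106), primitive streak H3K4me2 ES-only with the higher-scoring 50% (5 of 7, exact test, adjusted p = 0.0343) and mature tissue H3K4me2 EB-only without EB wild-type replicate 1 (4 of 7, exact test, adjusted p = 0.0317).

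Leaving out each library in turn loosens the criterion for regions, which raises counts by construction. Log2 peak number ranged from 0.71 to 1.501 for PRDM16 ES, -0.52 to 0.30 for PRDM16 EB, -0.10 to 0.18 for H3K4me1 ES, -1.19 to -0.61 for H3K4me1 EB, 0.30 to 0.48 for H3K4me2 ES and -0.41 to 0.02 for H3K4me2 EB. Wild-type-only and KO-only counts ranged from 10 to 227 and 41 to 461 for PRDM16 ES, 13 to 188 and 2 to 119 for PRDM16 EB, 2043 to 4528 and 2146 to 4353 for H3K4me1 ES, 4204 to 8724 and 911 to 3624 for H3K4me1 EB, 962 to 1949 and 5999 to 8774 for H3K4me2 ES and 1968 to 5589 and 821 to 1765 for H3K4me2 EB. ES-only and EB-only counts ranged from 16 to 243 and 5 to 169 for PRDM16, 6131 to 10767 and 5105 to 9787 for H3K4me1 and 6994 to 10537 and 2217 to 5013 for H3K4me2. The stage by genotype difference ranged from 0.62 to 0.91, passing throughout. The joint loss odds ratio ranged from 1.72 to 2.42 in ES cells and 0.758 to 1.33 in EB, where it reversed to 0.780 without H3K4me1 wild-type replicate 1, 0.758 without its replicate 2 and 0.772 without H3K4me2 KO replicate 1. The fold of PRDM16 peaks over H3K4me regions ranged from 8.12 to 9.12 in ES cells and 11.2 to 14.1 in EB. Passing list tests ranged from 1 to 3 in KO and 3 to 5 by stage. The Hox odds ratio in KO ES cells ranged from 9.37 to 19.8, and by stage the odds ratios ranged from 13.4 to 28.7 for cardiac, 4.59 to 21.2 for Hox, 10.6 to 17.2 for neuroectoderm and 8.62 to 20.6 for naive pluripotency genes.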

Other observations

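All tests here were chosen only after the result was seen. Genes with H3K4me2 in KO EB but not in wild-type EB overlapped by name with ES-only genes of the wild-type comparison, among them Nxph1, Lrrc4, Dtx4 and Lhx2. The hypothesis that regions of wild-type ES cells were kept in EB KO was suggested by these names. Of the 577 KO-only regions, 44.2% had a peak in both wild-type ES lists, against 40.5% of regions in 1 wild-type and 1 KO EB list (odds ratio 1.16, Fisher's exact test, two-sided p = 0.152). The test did not pass, which does not show that the shares are equal.

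Of 46 housekeeping and naive pluripotency genes, 32 had no H3K4me2 peak within 2500 bp of a gene end in 1 or both wild-type ES lists. Broad domains that escape the peak calls are a candidate explanation. Peaks of 7 kb and more scored below those of 3 to 4 kb in 16 of 16 H3K4me lists, and no peak in any list was wider than 8714 bp. A peak just outside the window would account for few of the 32 genes, since 15.6% had one within 10 kb in both lists.

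A chromosome gained in the KO line would raise its share of peaks in all 4 sets of H3K4me1 and H3K4me2. Chromosome 3 had the lowest adjusted p of chromosomes with a higher KO share in all 4 sets (0.0648), which neither passes the threshold nor excludes a gain.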
